A study of Schizosaccharomyces pombe with 2 samples.

How the data were processed

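Exponentially growing cells in rich YES medium were fixed with 1% formaldehyde for 15 min and quenched with 125 mM glycine, per the labels' protocols. Chromatin was sheared to 250 to 400 bp, and HA-tagged Abp1 was retrieved with a monoclonal anti-HA antibody. The groups, taken from the labels, were the Abp1-HA ChIP (1 library) and the input (1 library, no values analysed here). Reads were aligned with Bowtie 0.12.5, per the submitters' processing notes.

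The deposited values are a signal, 1 whole-number height per interval, as the authors listed it, with no header. All heights are 200 or more, and the values look like runs of positions at or above that level. The caller, the genome build, the treatment of reads with several matches, duplicate removal, any scaling, the use of the input and the read length are not given in the sources used here. Heights were used only to rank and describe intervals within the list. Starts were read as counted from 1 and ends as exclusive, since the last listed end on chromosome III was 2452884 and the chromosome has 2452883 bases.

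Positions were set against the RefSeq annotation of assembly ASM294v3. Since no build is named, midpoints of LTRs, 5S and tRNA genes were compared with the intervals over a range of offsets on the left and right side of each chromosome. The best offset was 0 or within 20 bp everywhere, for example 42 of 72 midpoints covered at offset 0 on the left side of chromosome I against a median of 1 over offsets. Coordinates are counted from 1.

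Features with an overlap of at least 1 bp, or interval midpoints for promoters, gene parts and intergenic space, were counted and compared with 10000 circular shifts of the list along each chromosome (two-sided, smallest p 2.00e-04), with Benjamini-Hochberg adjustment over 22 classes. The shift keeps widths and clustering. Promoters were the 500 bp upstream of the annotated gene start. Subtelomeres were the outer 50 kb of chromosomes I and II. Centromere spans were taken from the annotated centromeric noncoding RNAs and the mating-type span from the mat genes, both after the list was seen, as was the 200 bp limit that assigns an LTR to a Tf2 gene. The 13 gene lists (CENP-B family, core histones, ribosomal proteins, glycolysis, hexose transport and glucose repression, stress response, sexual differentiation, iron, phosphate, G1/S and mitotic transcription, wtf genes, heterochromatin and histone deacetylases, cell surface) were fixed before the data were examined and tested with Fisher's exact test. RNase P genes caught by the ribosomal prefix were removed afterwards, and 1 cell surface symbol had no match. Heights and gene-body coverage were compared by permutation tests with 100000 resamples.

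Genes were named by a rule fixed before the data were examined: all Tf2 genes, abp1, cbh1 and cbh2, the gene with the nearest start to each of the 15 highest intervals, and up to 4 members per list with the highest promoter interval. Ties in height were broken by genome order.

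Because many intervals lie at repeats, every 36-base window of the intervals, LTRs and tRNA genes was compared with the reference, exactly and, with bwa 0.7.19, at up to 3 mismatches. The window length is a choice made here. Of the 6893 intervals, 896 held a repeated window and 1288 one shared at up to 3 mismatches.

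Alternatives fixed before the data were examined were the highest 50% and 10% of intervals, other overlap rules, 400 independent random placements, promoters of 250 and 1000 bp, start codons, leaving out genes with a tRNA gene, LTR or Tf2 element upstream, other composition windows and heights divided by width. Merging within 100 bp for the class tests, leaving out intervals with repeated or shared windows, the LTRs with few shared windows, heights per merged region and the gene-body comparison were added after the list was seen. The tests were tested on simulated data. For the LTR class (238 features), 5% of 100 shifted lists without effect gave p under 0.05, and 20 planted intervals were detected in 100% of 20 simulations. The lists without effect were made by the same kind of shift as the test, so a share near 5% follows by construction. It says nothing about copies that share reads or about intervals enriched between genes. A simulated gene list of 20 genes with 10 of 200 planted promoters was detected in 100% of 50 simulations. Every one of these simulations gave the same counts, so that outcome was fixed and says nothing about weaker lists. Analyses used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.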

Results

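Chromatin immunoprecipitation and sequencing (ChIP-seq) of Abp1 was carried out in exponentially growing fission yeast, Schizosaccharomyces pombe. Abp1 is a homolog of CENP-B, the human protein that binds centromeric satellite DNA. The protein carried an HA tag and was retrieved with an anti-HA antibody from cells labelled wild type. The series holds 1 ChIP library and 1 input library, each the only replicate of its group. The values analysed here are 1 list of 6893 intervals from the ChIP library, each with a height. No values of the input library are analysed here, and its use in making the list is not given in the sources used here. Read depth is unknown, so no interval on any height can be given, and every p-value below compares positions within 1 list, not cultures. The series title names Tf2 retrotransposons and the rRNA gene repeat, so these were examined first.

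The list covered 308304 bases, or 2.45% of the 3 chromosomes. Most intervals were short and low. The median width was 4 bp (interquartile range 1 to 19 bp), 1900 intervals (27.6%) were 1 bp wide, and the median height was 218 (interquartile range 206 to 258), with no height under 200. Intervals lay close together, and joining those up to 100 bp apart left 1133 regions. Chromosome III held 24.2% of the intervals (95% exact binomial interval 23.2% to 25.3%) and 19.5% of the sequence (exact binomial test, two-sided, p = 5.69e-22). Because neighbouring intervals are not independent, the same test was made on regions, of which chromosome III held 24.2% (exact binomial p = 1.10e-04). Chromosome I held 39.97% of the intervals and 44.4% of the sequence (exact binomial p = 1.50e-13), which did not pass on regions (43.3%, exact binomial p = 0.492). Chromosome II held 36.1% of the sequence, 35.8% of the intervals (exact binomial p = 0.581) and 32.5% of the regions (exact binomial p = 0.0112).

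The highest intervals lay at long terminal repeats (LTRs), sequences that flank retrotransposons such as Tf2 and can remain as solitary copies. Which element each solitary LTR came from was not examined. Of 238 annotated LTRs, 166 (69.7%) carried an interval, against a mean of 13.9 when the list was shifted along the chromosomes, a ratio of 11.9 (circular-shift permutation test, adjusted permutation p = 4.00e-04, from the smallest p that the shifts can give). All 25 LTRs within 200 bp of a Tf2 gene carried one, 24 of them with a height of 57791, and so did 141 of the 213 other LTRs. The median height of the highest interval was 55446 over the 166 LTRs. If each read was counted at every copy, which is not known, heights at repeats sum over copies and cannot be compared with heights elsewhere. The height 57791 would then be 903 for each of the 64 LTRs at that height, or 348 over all 166. Intervals without a window shared at up to 3 mismatches reached at most 2698. Of the 119 intervals at 10000 or more, 112 overlapped an LTR and 6 the 18S, 5.8S and 28S rRNA genes. The remaining one, at chromosome III 814804 to 814949 with a height of 45521, lay outside both. The LTR ratio passed in every alternative run but varied: it was 3.69 with random placement, 5.12 without intervals holding a repeated 36-base window and 2.65 (24 LTRs) without those holding a window shared at up to 3 mismatches, against 19.1 with the highest 10% of intervals.

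All 13 Tf2 genes overlapped an interval, against 2.88 in shifted lists (ratio 4.51, adjusted permutation p = 4.00e-04), but the overlap was confined to their ends. Intervals covered a median of 1.42% of the coding sequence, and no base of the middle 80% of any of the 13. Tf2-1 (SPAC9.04, chromosome I 1465847 to 1469848) is an example: both flanking LTRs reached 57791, and an interval with a height of 214 lay inside its coding sequence. The same values were found for Tf2-2, Tf2-3, Tf2-4, Tf2-5, Tf2-6, Tf2-7, Tf2-8, Tf2-10, Tf2-12 and Tf2-13. Tf2-9 had an interval of 617 inside, and Tf2-11 had 1 LTR at 55568. The ratio was 7.10 with the highest 10% of intervals; with random placement of each interval it was 1.13 (adjusted permutation p = 0.434), and without intervals holding a repeated window no Tf2 gene carried one.

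**Figure D1:**
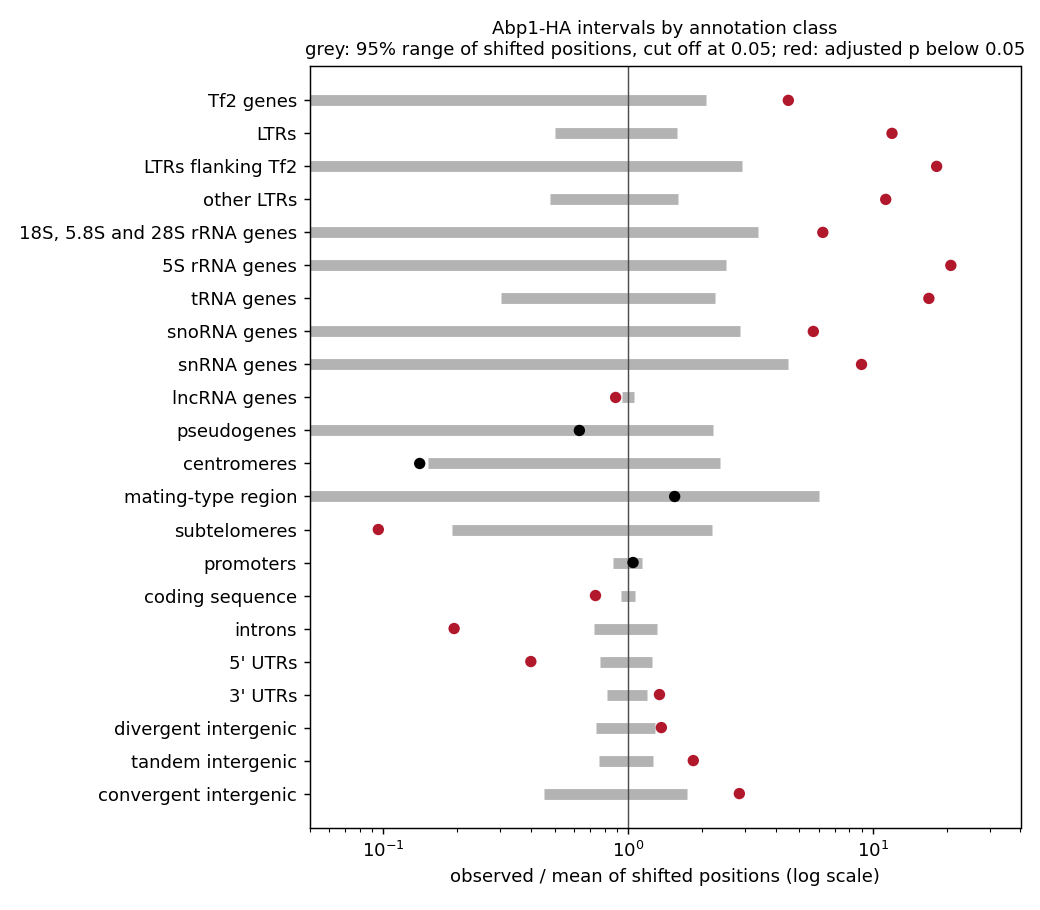
Observed number divided by the mean over shifted lists (x axis, log scale) for each annotation class; grey bars give the 95% range of shifted lists and red points an adjusted p under 0.05. 5S rRNA genes (20.8), LTRs next to Tf2 (18.2) and tRNA genes (16.9) lie farthest to the right, and subtelomeres (0.0953) farthest to the left. Copies of a repeat count as separate features.

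Both kinds of rRNA gene carried intervals. All 11 annotated 18S, 5.8S and 28S genes, at the ends of chromosome III, did so with heights of 23554 to 50069, against 1.76 in shifted lists (adjusted permutation p = 0.0082). Only 6 intervals made up this overlap, so the 11 genes are not separate sites. Of the 36 dispersed 5S genes, 33 did, against 1.59 (ratio 20.8, adjusted permutation p = 4.00e-04), and their heights lay between 5397 and 5638. If each read was counted at every copy, the median of 5571 over 33 copies would be 169 each, under the lowest listed height of 200. Copies may share reads and are then not independent. The class tests count each copy, so their p-values at LTRs, Tf2, rRNA and tRNA genes may be too small. With random placement the ratios fell to 1.70 for the 18S, 5.8S and 28S genes (from 6.23) and 8.45 for the 5S genes, both still past the threshold (adjusted permutation p = 0.00645), and with the highest 10% of intervals the 5S ratio was 35.1. These genes are repeats: the 5S ratio was 4.55 without intervals holding a repeated window (adjusted permutation p = 0.0147), and without intervals holding a window shared at up to 3 mismatches, no 18S, 5.8S or 28S gene and 3 5S genes carried one, which ended the 5S call (ratio 2.95, adjusted permutation p = 0.224). Counted by midpoints, 4 of the 11 18S, 5.8S and 28S genes held one, which ended that call (ratio 2.51, adjusted permutation p = 0.24). With 6 overlapping intervals, at most 6 of these genes could hold a midpoint, so this loss decides nothing.

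Transfer RNA genes also carried intervals. Their heights were lower, but heights at repeats may sum over copies. Neither input nor untagged values were analysed here, so whether intervals at RNA genes, rRNA genes included, reflect Abp1 or background stays open. Of 171 tRNA genes, 112 (65.5%) carried an interval, against 6.63 in shifted lists (ratio 16.9, adjusted permutation p = 4.00e-04), with a median height of 847. Among small nucleolar RNA genes 16 of 66 carried one (ratio 5.70, adjusted permutation p = 4.00e-04), and among small nuclear RNA genes 2 of 6 (ratio 8.97, adjusted permutation p = 0.0499). Long noncoding RNA genes carried fewer than shifted lists, 530 of 7133 (ratio 0.888, adjusted permutation p = 4.00e-04), and pseudogenes did not differ, with 2 of 32 (adjusted permutation p = 0.746). With random placement the tRNA ratio was 9.75 (adjusted permutation p = 0.00645) and the snoRNA ratio 2.17 (adjusted permutation p = 0.0183), and by midpoints the tRNA ratio was 27.4. The tRNA call ended without intervals holding a repeated window (ratio 2.38, adjusted permutation p = 0.0784) or a window shared at up to 3 mismatches (1.80, adjusted permutation p = 0.328); 162 of the genes hold such a shared window. In a split made after these values were seen, 7 of the 9 genes without one carried an interval (ratio 21.6, permutation p = 2.00e-04). The snRNA call ended with the highest 50% of intervals (ratio 4.91, adjusted permutation p = 0.375) and the highest 10% (7.94, adjusted permutation p = 0.275), each with 1 gene left, and with random placement (3.88, adjusted permutation p = 0.219). The lncRNA call ended without shared windows (0.935, adjusted permutation p = 0.125) and its ratio was 0.208 with random placement, under which pseudogenes passed (0.143, adjusted permutation p = 0.00645).

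**Figure D2:**
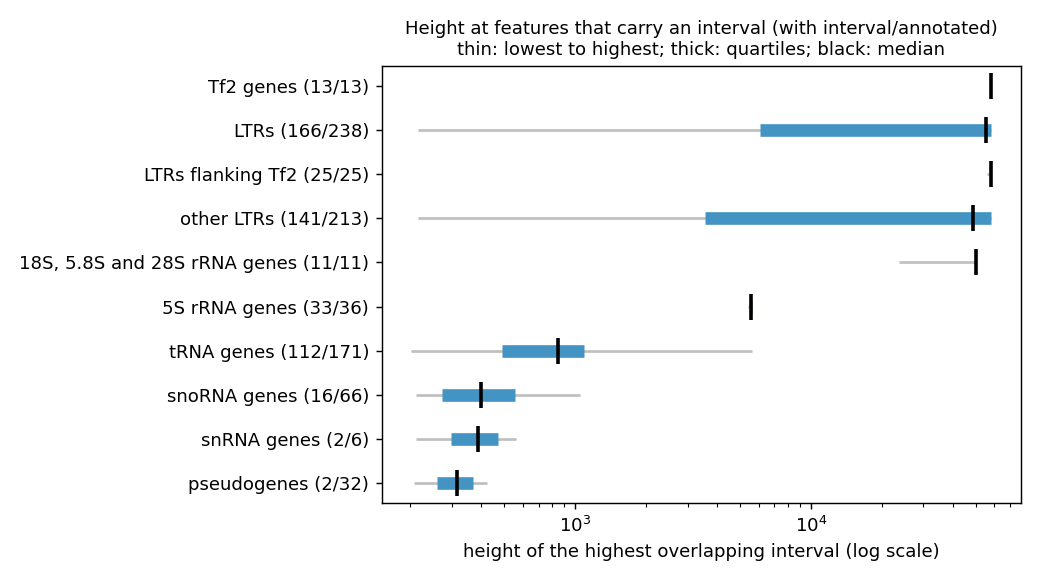
Height of the highest overlapping interval (x axis, log scale) at the features that carry one, with counts beside each class; thin lines run from lowest to highest, thick bars over the quartiles, and black marks are medians. The 33 5S genes lie between 5397 and 5638, and the median tRNA gene is at 847.

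Centromeres held few intervals. There were 12, all in centromere II, against a mean of 85.3 in shifted lists (ratio 0.141, adjusted permutation p = 0.056), so the difference did not pass the threshold; it did with the highest 50% of intervals (0.116, adjusted permutation p = 0.0465) and with random placement (0.140, adjusted permutation p = 0.00645). Centromeres I and III held none. The outer 50 kb of chromosomes I and II held 10, against 105 (ratio 0.0953, adjusted permutation p = 0.019), a call that ended with the highest 10% of intervals (0.197, adjusted permutation p = 0.141). All 10 lay within chromosome I 5541461 to 5541832, at and beside 1 LTR with a height of 14410, and joined into 1 region. The mating-type region held 16, against 10.3 (adjusted permutation p = 0.489). All 12 centromeric intervals held a repeated window, and 5 of the 10 subtelomeric ones held no shared window, though these 5 belong to the same LTR site. How reads with several matches were treated is not given in the sources used here.

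Relative to genes, interval midpoints were enriched in the space between genes. Ratios were 2.84 between convergent genes (adjusted permutation p = 7.00e-04), 1.84 between tandem genes (adjusted permutation p = 4.00e-04) and 1.37 between divergent genes (adjusted permutation p = 0.0197), and 1.34 in 3′ UTRs (adjusted permutation p = 0.0016). Midpoints were depleted in coding sequence (0.735), 5′ UTRs (0.400) and introns (0.194), each with an adjusted permutation p of 4.00e-04. The 500 bp upstream of genes held 1344 midpoints, against 1285 (adjusted permutation p = 0.543). For promoters the ratio was 0.884 with a 250 bp window and 0.865 from the start codon, neither past the threshold, but it passed with the highest 50% of intervals (1.16), merged regions (1.45) and the highest 10% (2.02). The 3′ UTR enrichment was lost on merged regions (1.06, adjusted permutation p = 0.558) and turned among the highest 10% (0.564), and the divergent call was lost without repeated (1.32, adjusted permutation p = 0.0704) or shared windows (1.30, adjusted permutation p = 0.125) and reached 2.99 among the highest 10%, where coding sequence was at 0.350, 5′ UTRs at 0.12 and tandem space at 3.16.

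Of 5113 protein-coding genes, 426 had an interval in the 500 bp upstream, and 2 of 13 gene lists stood apart (Fisher's exact test, two-sided, adjusted over the lists). In the phosphate homeostasis list, 4 of 6 genes had one (ratio 8.07, adjusted exact p = 0.00405): tgp1 at 846, the acid phosphatase gene pho1 at 745, pho4 at 214 and the phosphate transporter gene pho84 at 208. The last 2 heights are near the lowest listed height of 200. Intervals covered 79.6% of the pho84 body and 40.2% of pho1, against 11.1% of tgp1 and 0 of pho4. On chromosome II, pho84 ends at 4446200 and pho1 starts at 4447506, so they may not be independent. Among the wtf genes, which act in spore killing, 10 of 16 had an upstream interval (ratio 7.66, adjusted exact p = 9.59e-07), led by wtf15 (55446) and wtf13 (50785), and 9 of these 10 also have an LTR upstream. Glycolysis genes had 4 of 15 (ratio 3.22, adjusted exact p = 0.134), namely tdh1 at 331, eno101 at 302, fba1 at 288 and gpm1 at 210. The list passed when genes with a tRNA gene or LTR upstream were left out (ratio 5.19, adjusted exact p = 0.0404). With the highest 10% of intervals it had 0 of 15. These heights are near the floor of 200, and intervals covered 70.7% to 94.5% of the 4 gene bodies. Whether the upstream intervals are the edge of that coverage was not tested. Neither abp1 nor its relatives cbh1 and cbh2 had an upstream interval. The phosphate list no longer passed with the highest 50% of intervals (adjusted exact p = 0.341) or the highest 10% (adjusted exact p = 0.189). The same held with a 250 bp window (adjusted exact p = 0.176) and from the start codon (adjusted exact p = 0.267). The wtf list no longer passed without shared windows (adjusted exact p = 0.253). Nor did it when genes with a tRNA gene or LTR upstream were left out (1 of 4, adjusted exact p = 0.487).

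The other 9 lists did not pass. Heterochromatin and histone deacetylase genes had 4 of 21 (adjusted exact p = 0.298), namely raf2 at 57791, with an LTR upstream, swi6 at 1040, ago1 at 947 and chp1 at 737. Without intervals holding a shared window 2 of the 21 were left (adjusted exact p = 0.581), ago1 at 947 and swi6 at 254. Cell surface genes had 3 of 18 (adjusted exact p = 0.481) and hexose transport genes 2 of 12 (adjusted exact p = 0.572). The former were pfl2 at 491, adn3 at 277 and psu1 at 257, and the latter ght8 at 305 and rst2 at 202. Sexual differentiation genes had 0 of 20 (adjusted exact p = 0.751). Ribosomal protein genes had 13 of 138, core histone genes 1 of 10, stress response genes 2 of 20 and G1/S and mitotic genes 2 of 22, all with an adjusted exact p of 0.833, and iron homeostasis genes had 1 of 13 (adjusted exact p = 1). The highest ribosomal protein genes were rpl4102 (57791), rpl1001 (57162) and rps801 (41447), each with an LTR upstream, and rps1101 (2304). In the other lists these were hta1 (286, histone), hsp90 (5558) and trx2 (523, stress response), cdc18 (889) and adg1 (275, G1/S and mitotic) and vht1 (2459, iron).

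Intervals also ran along the bodies of particular genes, a comparison added after the list was seen. Glycolysis genes were covered over a mean of 53.0% of their span, against 1.30% for other genes (permutation test, adjusted permutation p = 8.67e-05, n = 15 genes). Cell surface genes were covered over 20.2% (adjusted permutation p = 8.67e-05) and ribosomal protein genes over 8.35% (adjusted permutation p = 8.67e-05). Phosphate genes (21.8%, adjusted permutation p = 0.00815 in the permutation test), hexose transport genes (15.2%, adjusted permutation p = 0.00686) and stress response genes (12.3%, adjusted permutation p = 0.00377) passed too. Members differed widely: the median coverage was 70.7% in the glycolysis list, 5.57% in the phosphate list and 0 in the other 4, and at least 50% was covered in 5 of 18 cell surface and 6 of 138 ribosomal protein genes. At least 50% of the span was covered in 60 genes, among them tdh1 (94.5%), eno101 (92.4%) and fba1 (88.6%); plb1 (99.6%), encoding a lysophospholipase, and pma1 (95.8%), encoding the plasma membrane proton pump, were chosen after their values were seen. Without genes holding a repeated window, the hexose transport and phosphate lists no longer passed (adjusted permutation p = 0.430 and 0.185).

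**Figure D3:**
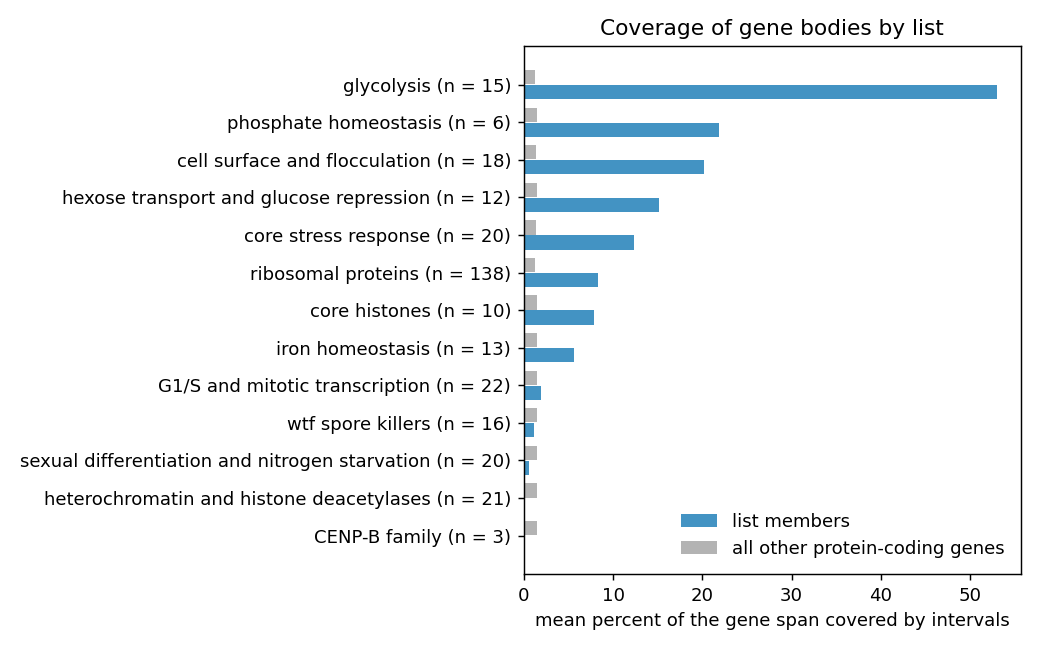
Mean percent of the gene span covered by intervals (x axis) for the members of each of 13 gene lists (blue) and for all other protein-coding genes (grey), from 1 library, so no error bars are drawn. Glycolysis genes reach 53.0%.

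The genes nearest to the 15 highest intervals were set by LTRs, since all 15 overlapped one. The highest, 58254 at chromosome II 4437506 to 4437842, lay upstream of SPBC8E4.03. The other 14 shared the height 57791 with other intervals, 59 in all, so genome order decided which were named: mis4, Tf2-1, fml1, ire1, Tf2-2, SPAC6B12.14C, imp4, rpl4102, amt3, Tf2-3, SPAPB2C8.01, cox8, ntr1 and iec5.

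Height differed between classes within the list, though heights at repeats may sum over copies. The median was 810 at LTRs against 217 elsewhere, 5571 at 5S genes against 218, 406.5 at tRNA genes against 218, and 226 in promoters against 217 (permutation test, adjusted permutation p = 2.50e-05 for each). Coding sequence was at 217 against 219 (adjusted permutation p = 0.116). On merged regions, since neighbouring intervals are not independent, all 5 differences passed (adjusted permutation p = 2.00e-05 for each), with medians of 55079 against 279 at LTRs, 5571 against 300.5 at 5S genes, 835 against 288 at tRNA genes, 749 against 263 in promoters and 274 against 423 in coding sequence; heights at repeat copies are still not independent. Divided by interval width, the tRNA difference turned to -54.9 and passed (adjusted permutation p = 1.00e-04), while the 5S (-21.2, adjusted permutation p = 0.219) and promoter (-3.46, adjusted permutation p = 0.464) differences turned negative without passing.

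Base composition around midpoints was lower in A+T than at shifted positions, 62.8% against 63.9% in 200 bp windows (circular-shift permutation test, p = 2.00e-04). Among the highest 10% of intervals it was 64.3%, or 0.39 percentage points above shifted positions (permutation p = 0.141). Among intergenic midpoints it was 67.5% against 68.1% (permutation p = 0.16). The 105 regions of 300 to 800 bp without shared windows and at least 400 high, a set defined after the list was seen, were higher in A+T, 68.4% against 63.9% (permutation p = 2.00e-04), but not detectably so at intergenic midpoints (permutation p = 0.388).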

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

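No paired analysis was possible because there is 1 ChIP library, 1 input library and no replicate. Alternatives that merged intervals for the tests, or left out intervals, LTRs or genes for holding repeated or shared windows, were chosen after seeing the data, and the cause of a change was not tested unless stated. Of the alternatives for the main results, 121 kept direction and side of the threshold, while 17 no longer passed, 9 newly passed, 10 changed direction and 6 counts moved. With the highest 50% of intervals, the ratio was 0.116 at centromeres and 1.16 at promoters, both now past the threshold, the phosphate list fell below it (4.23) and 1 list passed. With the highest 10%, subtelomeres (0.197) and the phosphate list (5.73) no longer passed, promoters did (2.02), 3′ UTRs turned to 0.564, A+T content to 0.39 percentage points above shifted positions, and 1 list passed. Merged regions, 1133 in place of 6893 intervals, gave 1.45 at promoters, past the threshold, lost the 3′ UTR call (1.06) and put the height in coding sequence lower by -149, past it. Without intervals holding a repeated window, the ratio was 0 for Tf2 genes, for LTRs next to Tf2, for 18S, 5.8S and 28S genes and, now past the threshold, for centromeres, because these intervals hold repeated windows by construction; tRNA genes (2.38) and divergent space (1.32) no longer passed. Without windows shared at up to 3 mismatches, the same 4 classes were again at 0, and 5S genes (2.95), tRNA genes (1.80, with intervals at genes that hold a shared window removed by construction), divergent space (1.30) and the wtf list (3.33) no longer passed, leaving 1 list. With midpoints, 18S, 5.8S and 28S genes gave 2.51, no longer past the threshold, though at most 6 of the 11 could hold a midpoint. With random placement, Tf2 genes gave 1.13, no longer past it, and centromeres 0.140, now past it. Promoters turned to 0.884 with 250 bp and 0.865 from the start codon, neither past the threshold, and the phosphate list fell to 5.97 and 4.74, no longer past it, leaving 1 list each. Without upstream windows that overlap a tRNA gene or LTR, the wtf list gave 4.81 and did not pass, and the glycolysis list gave 5.19 and did. Intergenic midpoints differed by -0.536 percentage points in A+T, no longer past the threshold. Divided by width, the height difference turned to -54.9 at tRNA genes, past the threshold, and to -21.2 at 5S genes and -3.46 in promoters, not past it. By mean rank, coding sequence lay lower by -237 and passed. Among genes without a repeated window, the coverage difference was 0.284 percentage points for hexose transport and 9.19 for phosphate, neither past the threshold. Unknown depth limits all heights.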

Other observations

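The tests of equal heights, of any coverage of ribosomal protein genes, of genes without a repeated window, of the short word, of tRNA genes by shared windows and of LTRs by unshared intervals were chosen only after the result was seen. Away from repeats, the list held 700 regions without a window shared at up to 3 mismatches, and the highest lay between genes. Those 100 with midpoints between divergent genes had a median height of 505 and a median span of 417 bp, against 238 and 37 bp for 284 in coding sequence. The 136 between tandem genes (273 and 73.5 bp) and the 41 between convergent genes (247 and 36 bp, none above 1042) were closer to coding sequence. The highest, all named after their values were seen, lay upstream of cam2 (2698, chromosome I 5138060 to 5138826), hac1 (2690, chromosome II 1208053 to 1208588), tim18 (2586, chromosome II 2035422 to 2036058), SPBC1289.14 (2476, chromosome II 4410779 to 4411277) and vht1, the biotin transporter gene (2459, chromosome I 4961109 to 4961623).

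Leaving out intervals with a shared window gave a tRNA ratio of 1.80 (adjusted permutation p = 0.328), but this removes by construction nearly all intervals at the 162 tRNA genes that hold such a window, where 1 gene kept one. A split of the genes, made after that value was seen, found that 7 of the 9 genes without a shared window carried an interval, and 6 of the 9 an interval free of shared windows, a ratio of 28.6 (circular-shift permutation test, p = 2.00e-04).

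Reads shared between repeat copies were weighed as the whole source of LTR intervals. Of 26 LTRs with no shared window, 6 carried an interval, a ratio of 4.26 to shifted lists (permutation p = 0.0048), but their median height of 28800 shows intervals reaching in from repeated neighbours. With intervals free of shared windows only, 4 of the 26 did (permutation p = 0.0254). So did 12 of 59 LTRs with at least 90% unshared windows (permutation p = 2.00e-04). Both are more than in shifted lists, as needed if shared reads were not the whole source, but LTRs are few and the 26 are among the 59. Intervals at repeats can also run past the LTR, as at chromosome I 1469836 to 1470375 beside an LTR ending at 1470247. A piece without a shared 36-base window may therefore be the edge of a repeat signal. Shifted lists were also not matched to the space between genes, where intervals were enriched. Shared reads are thus not excluded as the whole source. Whether each read was counted at every copy was asked of intervals above 1000 with equal heights: a share of 0.994 of 1838 pairs had a common 36-base word, but 1711 of them come from the tie at 57791 that prompted the test, so this share decides nothing. Without that tie, and at least 1000 bp apart, the share was 0.913 of 127 pairs, or a sharing pair at 21 of 29 tied heights, against 7.54% of pairs of unequal height, so counting at every copy may explain most ties and stays a hypothesis.

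Coverage along genes may follow transcription. Ribosomal protein genes, taken as a highly transcribed list, were covered by 7.09 percentage points more than other genes (permutation p = 2.00e-05), as that hypothesis needed. Of the 138, 67 were covered at all, against 402 of 4975 others (Fisher's exact test, p = 2.17e-34). The 7.09 percentage points restate the comparison given above and are not a separate test, and the median coverage was 0. Their mean of 8.35% lay below that of glycolysis (53.0%) and cell surface genes (20.2%), and transcription was not measured here. Shared reads were weighed too: in the 60 genes covered over at least 50%, 14.1% of covered bases lay in repeated windows, between the 50% that would have counted for this and the 10% that would have counted against, so it cannot be told apart for the 60 as a set. In the 42 of them without a repeated window, 0.223% of covered windows had another match at up to 3 mismatches, but leaving out repeated windows largely fixes this share, which was 1.29% in 319 other covered genes without one and 18.9% in all 60, so it decides nothing. Without genes holding a repeated window, the differences from other genes were still past the threshold for glycolysis (50.1 percentage points), cell surface (21.9) and ribosomal protein genes (5.79), which argues against exactly repeated windows as the whole source of these. Whether coverage reflects Abp1 or a background of transcribed chromatin stays open, since neither input nor untagged values were analysed here.

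A short word recurred in part of a set of 105 narrow peaks, among them 14 of the 37 on chromosome I. The set was defined after looking at the list as regions of 300 to 800 bp without shared windows and at least 400 high. ATATAATA, picked on chromosome I, occurred in 17 of 68 such peaks on chromosomes II and III. It occurred in 65 of 1360 intergenic windows of matched A+T content, a ratio of 5.23 (Fisher's exact test, p = 6.70e-08), which argues against A+T content alone. Those windows were not matched for position relative to genes. Of the 105 peaks, 55 lay between divergent and 34 between tandem genes, so a word common upstream of genes was not excluded. Chromosomes II and III were not fully held out: words of several lengths had been listed over the whole genome beforehand, this one among them, and the word length was set after that, so the p is too small by an unknown amount. Among LTRs, 116 of 166 with an interval held the word and 14 of 72 without did, but LTRs are copies of each other. Whether Abp1 recognises this word is a hypothesis that these data cannot settle.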
